A study of Mus musculus with 12 samples.

How the data were processed

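RNA was sequenced from CD45-negative cells of lung tumours, the fraction left when leukocytes, which carry CD45, are removed. The tumours were grown in C57BL/6 mice whose Kras allele is switched to an activated form and whose p53 alleles are deleted by a recombinase. Per the labels, treatment began after 25 weeks of tumour growth and lasted 2 weeks, with 3 intraperitoneal injections per week of 10 mg/kg of an antibody. The antibody was either anti-Ly6G, which is used to deplete neutrophils, or a control IgG. Libraries were made with a stranded poly(A) kit from 500 ng of total RNA extracted with Trizol. The 12 libraries are 6 from anti-Ly6G mice, numbered 1 to 6, and 6 from control IgG mice, numbered 8, 9, 10, 13, 14 and 15. The labels also class each sample by neutrophil infiltration: low in anti-Ly6G libraries 1, 2, 4, 5 and 6 and in control IgG library 14, and high in anti-Ly6G library 3 and in control IgG libraries 8, 9, 10, 13 and 15. They do not say how infiltration was measured or where low was parted from high, so the infiltration and concordant comparisons rest on a label of unknown basis. The labels do not say whether each library is from a mouse of its own, so the p-values measure the spread between these samples.

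The submitters' processing notes list bcl2fastq 2.17, cutadapt 1.4.2, STAR, featureCounts 1.4.4 and DESeq2 with genome build mm10. They give no strand setting or annotation release. The deposited counts are whole numbers of reads per Ensembl gene for 39017 genes, and the 12 deposited files per sample were equal to the columns of the deposited series table in 12 of 12 cases. A second deposited table holds DESeq2-transformed log2 values made by the authors for 16752 genes. Every gene in the deposited log2 table had at least 61 reads over the 12 libraries, and no gene left out of it had more than 60. The log2 table was used for an alternative fit and the counts for everything else. Total counts per library ranged from 24727764 in control IgG library 9 to 51130567 in control IgG library 10. Gene positions came from the GENCODE M21 annotation of the same genome build, which held 37607 of the 39017 identifiers. The annotation release used for counting was not stated, and matching was by identifier.

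The 3 sample comparisons were fixed before the data were examined. The treatment comparison set 6 anti-Ly6G against 6 control IgG libraries. The infiltration comparison set the 6 libraries labelled low against the 6 labelled high, with differences given as low minus high. The concordant comparison set the 5 anti-Ly6G libraries with a low label against the 5 control IgG libraries with a high label, and it shares its 10 libraries with the other comparisons. Genes were filtered with filterByExpr, counts were scaled by trimmed mean of M values (TMM) factors, and each gene was tested by the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. The Benjamini-Hochberg threshold was 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. CPM values are read counts scaled by library size and TMM factor to the usual per-megaread unit. DESeq2 1.42.0, limma-voom 3.58.1 and limma-voom with sample quality weights were run beside edgeR. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

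Gene lists were fixed before the data were examined: 36 lists with 486 entries, covering pathways, the cell types of lung and tumour, and leukocyte types that the CD45 gate should have removed. Of the 486 entries, 476 were matched by the symbol in the count table, 7 by the GENCODE symbol and 3 by neither (Hbb-b1, Hbb-b2 and Ahsp). The pathway lists were hypoxia, mesenchymal genes, angiogenic factors, gastrointestinal and dedifferentiation genes, neutrophil-recruiting cytokines, interferon-stimulated genes, MHC class I and class II presentation, checkpoint ligands, cell cycle, p53 targets, TGF-beta targets, NF-kappaB targets, NRF2 targets, and immediate early and stress genes. The cell type lists were epithelial, alveolar type I and type II, club, ciliated, neuroendocrine, mesothelial, muscle, adipocyte, blood endothelial, lymphatic, pericyte, fibroblast, pan-leukocyte, neutrophil, macrophage, T cell, B cell, natural killer, erythroid and platelet markers. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry. The adipocyte and natural killer lists had fewer measured members and were not tested, which left 34 lists per comparison. Camera compares a list with all other genes. The one-way test of fry asks whether the list's genes move on balance in the same direction, and its mixed test whether they change at all. A list's score in a library was the mean of log2(CPM + 0.5) over its measured members. Scores were compared by exact two-sided permutation over 924 arrangements (252 for 5 against 5 libraries). Adjusting the edgeR p-values of a list's members over that list alone was not among the tests fixed before the data were examined. Such an adjustment does not allow for the choice of the list.

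Genes are named by a rule fixed before the data were examined. It takes, among genes with an average CPM of at least 1 that are not predicted loci, up to 12 genes in each direction with the largest change past the edgeR threshold, and where fewer than 5 pass in a direction the 10 genes of smallest p. It adds up to 4 members of smallest p from each list that passed camera, and 19 genes named whatever their values. No gene passed by edgeR, so the 10 of smallest p stand in their place. Most genes named outside the rule are marked as chosen after their values were seen. Exceptions without a mark include Xist, Ddx3y, the most abundant transcripts, and further members of the neutrophil and immediate early lists.

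Tested on simulated data with 200 changed genes, edgeR found 38% of the 2-fold and 75.5% of the 4-fold changes in the treatment design, 48% and 82.5% in the infiltration design, and 32% and 81% in the concordant design, with 1 to 7 false calls. DESeq2 found 112 to 131 of the 200 genes changed 2-fold and made 22 to 30 false calls. For 4-fold changes it found 165 to 181 and made 34 to 47 false calls. The simulated genes varied independently of each other, with no library standing apart and no close pair of libraries. The simulated shares and numbers of false calls therefore need not hold for the real libraries. The alternatives tried were 3 other scalings, other count filters, DESeq2, limma-voom with and without sample weights, a non-robust fit, a threshold of 0.1, a leukocyte covariate, the other label as a covariate, another pseudocount, and leaving out each library. Alternatives added after the data were seen were a limma fit to the deposited log2 values, the closest pair of libraries summed, and the covariate fits without library 3 or 14. Counts from 100 of the 462 possible splits of the 12 libraries (126 for the 10) were drawn with a fixed seed. Alternative splicing, sequence variants and the reads themselves were not analysed here.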

Results

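The dataset holds 12 RNA-seq libraries of CD45-negative cells from mouse lung tumours driven by activated Kras and loss of p53. Of these, 6 came from tumours treated with anti-Ly6G and 6 from tumours treated with control IgG. Per the labels, 5 of the 6 anti-Ly6G samples and 1 of the 6 control IgG samples had low neutrophil infiltration. Total counts were 37978725, 42643533, 40153410, 38547331, 35878447 and 36968434 in anti-Ly6G libraries 1 to 6. They were 27988100, 24727764, 51130567, 30255846, 33315319 and 48725972 in control IgG libraries 8, 9, 10, 13, 14 and 15. The most abundant transcript in each library was Sftpc or Sftpb, surfactant protein genes of alveolar type II cells, with 1.84% to 3.35% of counts. The first and second principal components of log2 CPM held 25.1% and 20.6% of the variance, and anti-Ly6G library 3 lay farthest out at -95.7 on the first. It also had the lowest TMM factor, 0.846. Control IgG library 13 had 4.31 CPM of Xist, a transcript of female cells, and 77.8 CPM of the Y-linked gene Ddx3y, while the other 11 libraries had at least 1598 CPM of Xist and at most 0.0804 CPM of Ddx3y. For depth, mitochondrial share and the other library measures no difference between groups passed (smallest adjusted p 0.779 over 24 exact permutation tests).

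**Figure D1:**
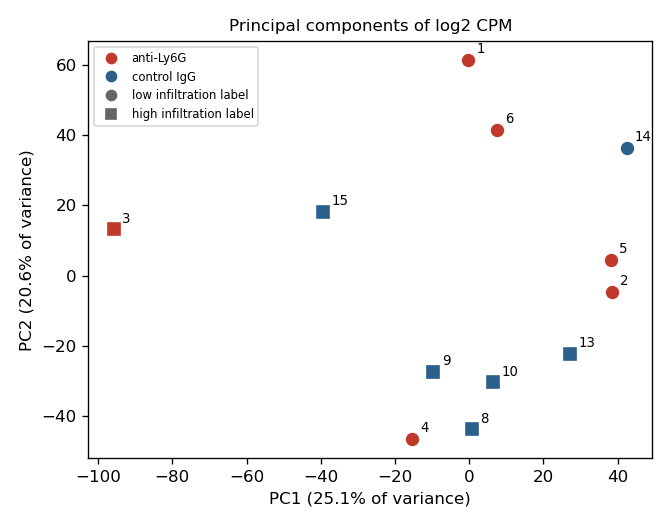
Principal components of log2 CPM for the 12 libraries, with the first component on the horizontal axis (25.1% of variance) and the second on the vertical axis (20.6%). Colours show the antibody, shapes the neutrophil infiltration label and numbers the library; anti-Ly6G library 3 stands apart at -95.7 on the first component.

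Neutrophil transcripts were scarce in this CD45-negative fraction. Ly6g, which encodes the antigen bound by the depleting antibody, had 4 reads over all 12 libraries and at most 1 read in any library, so it was below the count filter and its change was not detectable at this depth. S100a8 and S100a9, abundant in neutrophils, reached at most 1.43 and 2.82 CPM, and Csf3r, the receptor of the growth factor for neutrophils, at most 1.34 CPM. Higher levels came from Cd177 (at most 233 CPM), Ltf (33.5), Slfn4 (30.7), Cxcr2 (16.2) and Mmp9 (10.1). Over all 12 libraries Cd177 had 28543 reads and Ltf 4207, against 246 for S100a8 and 288 for S100a9. Whether cells other than neutrophils gave these reads was not tested, so the mean marker level need not track neutrophils. The mean log2 level of the 11 measured neutrophil markers was 0.890 ± 0.621 (SD, n = 6) with anti-Ly6G and 1.19 ± 0.340 with control IgG, a difference within the spread between libraries (exact permutation p = 0.338, adjusted p = 0.617 over 10 tests). It was 0.797 ± 0.610 in the low and 1.28 ± 0.201 in the high infiltration libraries (exact permutation p = 0.0844, adjusted p = 0.339). Without anti-Ly6G library 4 the exact permutation p for low against high was 0.0130 before adjustment. The B cell markers were at 0.599 ± 0.239 with anti-Ly6G and 0.928 ± 0.301 with control IgG (exact permutation p = 0.0649, adjusted p = 0.339, n = 6 each). The pan-leukocyte markers were at 2.05 ± 0.659 and 2.35 ± 0.448 (exact permutation p = 0.370, adjusted p = 0.617, n = 6 each), and the macrophage and T cell markers differed by -0.0942 and -0.0122 between antibodies (adjusted exact p 0.890 and 0.961).

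The treatment comparison asked which genes of the tumour fraction differed between depleting and control antibody. With anti-Ly6G, blood endothelial markers were lower, with 19 of 20 below control and a median log2 fold change of -0.53, and immediate early and stress genes were higher, with 12 of 14 above control and a median of 0.36. NF-kappaB targets (12 of 14 higher, median 0.18), MHC class I presentation genes (11 of 12, 0.47) and hypoxia-induced genes (26 of 35, 0.13) were also higher. Cell cycle genes (18 of 26 lower, median -0.25), B cell markers (3 of 5, -0.64) and club cell markers (6 of 8, -0.20) were lower. Camera put these 8 of 34 lists past the threshold at the preset correlation. With an estimated correlation none passed: adjusted p = 0.679 with an estimated correlation for the endothelial list, 0.834 for the MHC class I and cell cycle lists, and 0.655 for the other 5. Fry called 0 lists.

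Of the endothelial list, Egfl7, a secreted vessel protein, had a log2 fold change of -0.64 ± 0.27 (SE, 6 against 6 libraries), Esam, an endothelial adhesion molecule, -0.44 ± 0.22, Sox17, an arterial transcription factor, -0.89 ± 0.47, and Ramp2, an adrenomedullin receptor component, -0.71 ± 0.41. Among immediate early genes, Atf3, a stress-induced transcription factor, averaged 657 ± 186 CPM (SD) with anti-Ly6G and 349 ± 151 with control IgG, a log2 fold change of 0.91 ± 0.27. Fos stood at 0.60 ± 0.27, Fosb at 0.55 ± 0.28 and Jund at 0.66 ± 0.37. The NF-kappaB members Nfkbia, the inhibitor that the pathway induces, and Tnfaip3 stood at 0.61 ± 0.21 and 0.57 ± 0.30, and Ier3 at 0.52 ± 0.24. The hypoxia members of smallest p were Hk2, a hexokinase, at 0.55 ± 0.14, Ankrd37 at 0.75 ± 0.23, Bhlhe40 at 0.46 ± 0.17 and Pfkp at 0.46 ± 0.27. Ccnb2 (-0.60 ± 0.21), Cenpf (-0.44 ± 0.23), Ccnb1 (-0.62 ± 0.33) and E2f1 (-0.39 ± 0.24) led the cell cycle list. Igkc, an immunoglobulin light chain, was lower in all 6 anti-Ly6G libraries than in any control library, at 0.239 ± 0.135 against 1.04 ± 0.657 CPM (SD), and passed when adjusted over the list alone, with Igj at -1.04 ± 0.51, Ighm at -0.64 ± 0.50 and Cd79a at 0.22 ± 0.36. Psmb9, B2m, H2-K1 and Tap1 of the MHC class I list had log2 fold changes of 0.67 ± 0.44, 0.66 ± 0.49, 0.52 ± 0.39 and 0.52 ± 0.46. Of the club cell list, Cyp2f2 stood at -1.09 ± 0.61, Gabrp at -1.63 ± 0.99, Scgb1a1 at -0.65 ± 0.86 and Aldh1a7 at -0.18 ± 0.31.

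No gene passed by edgeR among 15324 tested (smallest adjusted p 0.997). An unadjusted p under 0.05 was found for 550 genes, 354 higher and 196 lower, where chance gives 766. DESeq2 called 1 gene, limma-voom 0, and limma-voom with sample weights 1385, of which 627 were higher. The DESeq2 gene was Gfra1 (ENSMUSG00000025089, chromosome 19, 58235604 to 58455909), which encodes a co-receptor for glial cell line-derived neurotrophic factor. It averaged 7.12 ± 5.85 CPM (SD, n = 6) with anti-Ly6G and 0.758 ± 0.254 with control IgG, with a log2 fold change of 3.23 ± 0.74 and an adjusted p of 0.0161 by DESeq2. Anti-Ly6G library 3 had 0.147 CPM of Gfra1, below every control library (0.382 CPM or more). The highest levels, 15.3 and 12.3 CPM, were in anti-Ly6G libraries 1 and 6, the pair of libraries closest to each other. The gene of smallest p by edgeR was Mtus1 (ENSMUSG00000045636, chromosome 8, 40990914 to 41133726), a microtubule-associated gene. Its level of 145 ± 18.2 CPM against 95.7 ± 15.1 was higher in all 6 anti-Ly6G libraries than in any control library, with a log2 fold change of 0.60 ± 0.13. The amino acid transporter Slc38a4 behaved likewise (41.6 ± 11.3 against 19.2 ± 6.81 CPM, log2 fold change 1.12 ± 0.25). The metallothionein gene Mt2 averaged 255 ± 46.4 against 127 ± 40.5 CPM, a log2 fold change of 1.003 ± 0.23. The others of the 10 genes with the smallest p were Clcn2, a chloride channel (-0.75 ± 0.18), Sema3f, a semaphorin (-0.67 ± 0.16), Hk2, Ccdc136 (1.49 ± 0.38), Smoc1, a secreted matrix protein (-5.54 ± 1.43), and Fam20c, a Golgi kinase (0.91 ± 0.24). The Smoc1 change was carried by control IgG libraries 8 and 9 (24.9 and 18.7 CPM), while control IgG libraries 14 and 15 (0.0923 and 0.0848 CPM) lay below anti-Ly6G libraries 2 and 4 (0.370 and 0.393 CPM). In 41 genes (0.268%) the groups did not overlap, where chance gives 0.216%.

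None of the genes of neutrophil biology and of the tumour that were named in advance passed by edgeR (adjusted p 0.997 for each that was tested). Log2 fold changes with anti-Ly6G were -0.56 ± 0.45 for S100a8, -0.41 ± 0.89 for S100a9, -0.11 ± 0.46 for Csf3r and 0.02 ± 0.39 for Ptprc, which encodes CD45. The neutrophil-attracting chemokines Cxcl1, Cxcl2 and Cxcl5 stood at 0.60 ± 0.41, 0.91 ± 0.40 and 0.38 ± 0.62. Hif1a, the oxygen-regulated transcription factor, stood at 0.17 ± 0.18, and its targets Vegfa, Slc2a1 and Car9 at 0.12 ± 0.20, 0.16 ± 0.15 and 0.65 ± 0.67. Snai1, a driver of epithelial-mesenchymal transition, stood at -0.36 ± 0.36, and Cd274, an immune checkpoint ligand, at 0.49 ± 0.47. Sftpc, Pecam1 and Mki67 stood at -0.37 ± 0.27, -0.52 ± 0.46 and -0.24 ± 0.27, and Kras and Trp53 at 0.08 ± 0.19 and -0.26 ± 0.25. The signs for S100a9, Csf3r, Ptprc, Vegfa and Kras turned when certain libraries were left out.

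Among pathway lists that camera did not call in the treatment comparison, interferon-stimulated genes were nearest, with 17 of 21 higher and a median of 0.20 (adjusted p = 0.0520), followed by neutrophil-recruiting cytokines, with 9 of 14 higher and a median of 0.30 (0.0806). Gastrointestinal and dedifferentiation genes had 7 of 17 higher and a median of -0.11 (0.289), mesenchymal genes 7 of 18 and -0.11 (0.333), and angiogenic factors 4 of 16 and -0.11 (0.738). NRF2 targets had 2 of 9 higher and a median of -0.11, with a mean of 0.02 (adjusted p = 0.542). TGF-beta targets had 7 of 14 higher and a median of -0.01, while camera ranked the list upward (0.616). For p53 targets, 5 of 12 were higher with a median of -0.05 (0.789). Checkpoint ligands had 5 of 8 higher and a median of 0.13, and MHC class II genes 4 of 8 and -0.01 (0.8295 for both).

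Several treatment list calls were lost when single libraries were left out. The endothelial and immediate early calls held without each library in turn, with an endothelial median of -0.93 without library 4 and an immediate early median of 0.60 without library 14. The B cell and club medians without library 4 were -1.04 and -0.44. NF-kappaB was lost without library 3 (median 0.02, adjusted p = 0.386) and MHC class I without library 4 (median 0.00128, adjusted p = 0.562), 8 or 9. B cell was lost without 3 (median -0.50) or 15 (-0.37), against -0.64 in the main fit. Hypoxia was lost without 2, 4, 9 or 15 (adjusted p 0.111 to 0.194), with medians of 0.0646 to 0.0960 against 0.13 in the main fit. Cell cycle was lost without 1, 3, 6, 8 or 9 (0.0511 to 0.421), with medians of -0.236 to -0.123. Club was lost without 1, 2, 6, 9, 10 or 14 (0.0541 to 0.356). Its median, -0.20 in the main fit, was -0.0770 without 1, -0.0935 without 2, -0.145 without 6 and -0.0779 without 14. Without 9 and 10 it was -0.231 and -0.267, no smaller in size than in the main fit. With the infiltration label as a covariate, the endothelial median was 0.29 (adjusted p = 0.300), the immediate early median -0.37 (0.183) and the MHC class I median -0.00202 (0.937), and edgeR called 9 genes, or 1 gene when library 3 or library 14 was also left out.

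The infiltration comparison asked what separated the 6 libraries labelled low from the 6 labelled high in neutrophils, whichever antibody was given. All 14 immediate early and stress genes were higher in the low infiltration libraries, with a median log2 fold change of 0.87, and 12 of them passed when adjusted over the list alone (0 over all genes by edgeR, 2 by DESeq2). The adjustment over the list alone was not planned and does not allow for this list being picked among all lists tested. All 20 blood endothelial markers were lower, with a median of -0.84. The immediate early score was 8.94 ± 0.354 (SD, n = 6) in the low and 8.13 ± 0.337 in the high libraries, and the endothelial score 4.22 ± 0.789 and 5.18 ± 0.382. On the immediate early list, anti-Ly6G libraries 1 and 6 scored 9.29 and 9.15. They were the pair of libraries closest to each other and were counted as separate samples. MHC class I genes were higher (12 of 12, median 0.54), and mesenchymal genes (13 of 18, -0.35) and neutrophil markers (9 of 11, -0.60) were lower.

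The transcription factor gene Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) averaged 1959 ± 464 CPM (SD, n = 6) in the low libraries and 1022 ± 189 in the high ones, with every low library above every high one and a log2 fold change of 0.94 ± 0.18. The gap was narrow, with 1369 CPM of Fos in anti-Ly6G library 5, labelled low, and 1355 CPM in control IgG library 10, labelled high. Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795), an orphan nuclear receptor gene induced within minutes of stimulation, stood at 280.0 ± 68.2 against 144 ± 31.5 CPM, a log2 fold change of 0.96 ± 0.19. DESeq2 called both, with adjusted p of 0.00193 for Fos and 0.00418 for Nr4a1. Fosb and Jun, partners or relatives of Fos, had log2 fold changes of 0.85 ± 0.22 and 0.87 ± 0.23. Egr1, Egr2, Atf3, Ier2, Junb, Jund, Dusp1 and Zfp36 also passed when adjusted over the list alone, with log2 fold changes from 0.51 for Zfp36 to 0.95 for Egr2. The heat shock genes Hspa1a and Hspa1b stood at 0.37 ± 0.41 and 0.40 ± 0.34 and did not pass. Without any given library, 10 to 12 of the 14 passed over the list alone. With the antibody as a covariate 10 passed, and 3 when library 14 was also left out.

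Among endothelial markers, Ramp2 stood at -1.04 ± 0.36 (SE, 6 against 6 libraries), Sox17 at -1.17 ± 0.43, Aplnr, the apelin receptor, at -1.13 ± 0.42, and Emcn, a sialoglycoprotein of capillaries and veins (chromosome 3, 137341067 to 137432185), at -1.13 ± 0.42, with 15.2 ± 13.3 CPM (SD) in the low and 33.2 ± 11.1 in the high libraries. None of the 20 passed when adjusted over the list alone, and 9 had an unadjusted p under 0.05. Anti-Ly6G library 4 had the highest endothelial score of all 12, 5.602, although labelled low, and its leukocyte score of 3.32 was the highest as well. Without library 4 edgeR called 90 genes, 13 higher and 77 lower (smallest adjusted p 0.00161). Among them were 7 members of the endothelial list and the vessel genes Thbd, Nos3, Cd34 and Icam2, which were chosen after their values were seen. Leaving out any other single library gave 0 genes. Library 4 was singled out by its high endothelial score, so the endothelial genes called without it are no separate support. The endothelial median without library 4 was -1.29.

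**Figure D2:**
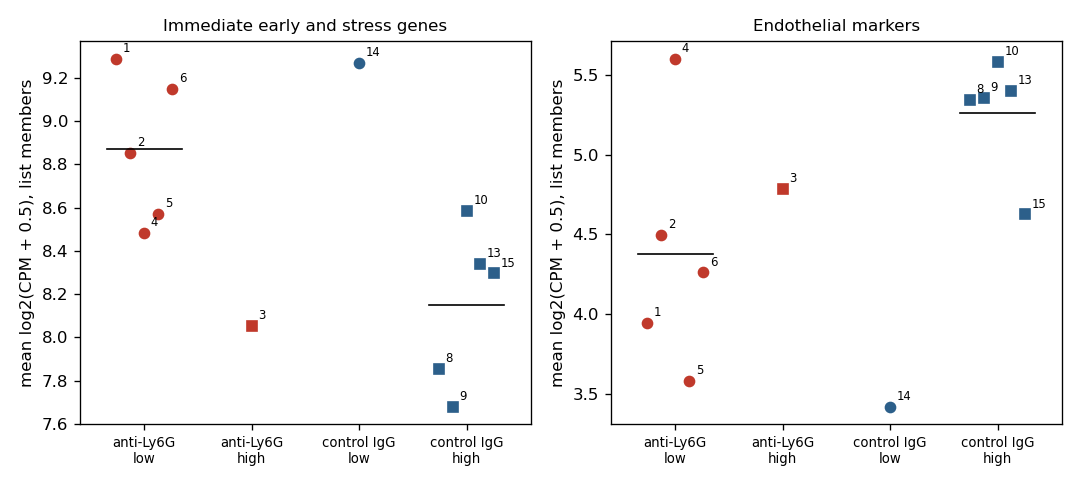
Mean log2(CPM + 0.5) of the immediate early and stress list (left) and the endothelial list (right) in each library, with numbers naming the libraries, columns the 4 combinations of antibody and infiltration label, and bars the means of columns with 5 libraries. In the immediate early panel, control IgG library 14, labelled low, lies at 9.27, above the other 5 control libraries at 7.68 to 8.59, and anti-Ly6G library 3, labelled high, at 8.05, below the other 5 anti-Ly6G libraries at 8.48 to 9.29; in the endothelial panel anti-Ly6G library 4 is highest at 5.602.

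Camera put 5 of 34 lists past the threshold at the preset correlation: immediate early (adjusted p = 9.73e-20), endothelial (1.01e-17), MHC class I (0.0102), mesenchymal (0.0151) and neutrophil (0.0437). With an estimated correlation none passed: adjusted p = 0.104 with an estimated correlation for immediate early, 0.664 for endothelial and 0.8294 for each of the other 3 lists. Fry called the immediate early list in both its one-way test (adjusted p = 0.0417) and its mixed test (0.00764), and called none of the others. By exact permutation of the scores, the immediate early list had p = 0.00649 (adjusted p = 0.221 over 34 lists) and the endothelial list p = 0.0281 (adjusted p = 0.478). The immediate early and endothelial camera calls held without each library in turn. MHC class I was lost without library 4 (median 0.13, adjusted p = 0.255), 8 or 9, mesenchymal without 5, 8, 9, 10 or 14 (adjusted p 0.0824 to 0.186), and neutrophil without 1, 5, 6, 8, 10, 13, 14 or 15 (0.0529 to 0.169). With the antibody as a covariate the adjusted p of MHC class I was 0.263 and that of the neutrophil list 0.221, and with a leukocyte covariate the neutrophil list had 0.136. Without library 4 the neutrophil and mesenchymal medians were -1.44 and -0.80.

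Of the mesenchymal list, Mmp3, a matrix metalloproteinase, stood at -4.15 ± 1.17 (SE, 6 against 6 libraries), Vim, an intermediate filament gene, at -0.81 ± 0.46, Itga5 at -0.72 ± 0.42 and Fn1, which encodes fibronectin, in the other direction at 0.66 ± 0.37. The Mmp3 level in the high libraries rested on anti-Ly6G library 3 (99.98 CPM) and control IgG library 10 (61.7 CPM), the other 4 lying at 1.498 to 6.64 CPM and the low libraries reaching 4.24 CPM, and its log2 fold change was -3.24 without library 3. Among neutrophil markers Ltf stood at -1.21 ± 0.68, Slfn4 at -1.75 ± 1.14, Retnlg at -1.03 ± 0.73 and S100a8 at -0.60 ± 0.45; Ltf is also made by airway glands. Without library 15 Slfn4 stood at 0.30, and without library 3 Ltf at -0.68. The MHC class I members Psmb9, Tap1, Tap2 and Psmb8 stood at 0.81 ± 0.42, 0.75 ± 0.44, 0.43 ± 0.26 and 0.47 ± 0.31.

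No gene passed by edgeR among 15324 tested (smallest adjusted p 0.454). There were 1297 genes with an unadjusted p under 0.05, 695 higher and 602 lower, where chance gives 766. DESeq2 called 47 genes, 39 higher and 8 lower, limma-voom 0, and limma-voom with sample weights 1606, of which 668 were higher. The gene of smallest p was Gfra1, at 7.26 ± 5.65 CPM (SD, n = 6) in the low and 0.613 ± 0.318 in the high libraries. Its log2 fold change was 3.57 ± 0.65, with an adjusted p of 8.41e-06 by DESeq2. Every low library lay above every high one, but control IgG library 14, labelled low, barely did so. It had 1.015 CPM against 1.011 in control IgG library 8, labelled high. The other low libraries, all with anti-Ly6G, had 2.15 CPM or more, so library 14 lay at the control level. After it came Pard3, a cell polarity scaffold (141 ± 13.1 against 94.1 ± 13.2 CPM, log2 fold change 0.58 ± 0.12), and Pla2g6, a phospholipase (119 ± 23.03 against 71.5 ± 10.2 CPM, 0.73 ± 0.15). The spectrin gene Sptbn2 stood at 1.26 ± 0.26, Ccdc88b at 0.93 ± 0.19, Fam26e, of a calcium-modulated channel family, at 1.82 ± 0.38, Tpst1, a tyrosine sulfotransferase, at 0.75 ± 0.16 and Trerf1, a transcriptional regulator, at 2.16 ± 0.45. All 10 genes of smallest p, Fos and Nr4a1 included, were higher in the low libraries and were called by DESeq2 (adjusted p 8.41e-06 to 0.0123). In 53 genes (0.346%) the groups did not overlap, where chance gives 0.216%.

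**Figure D3:**
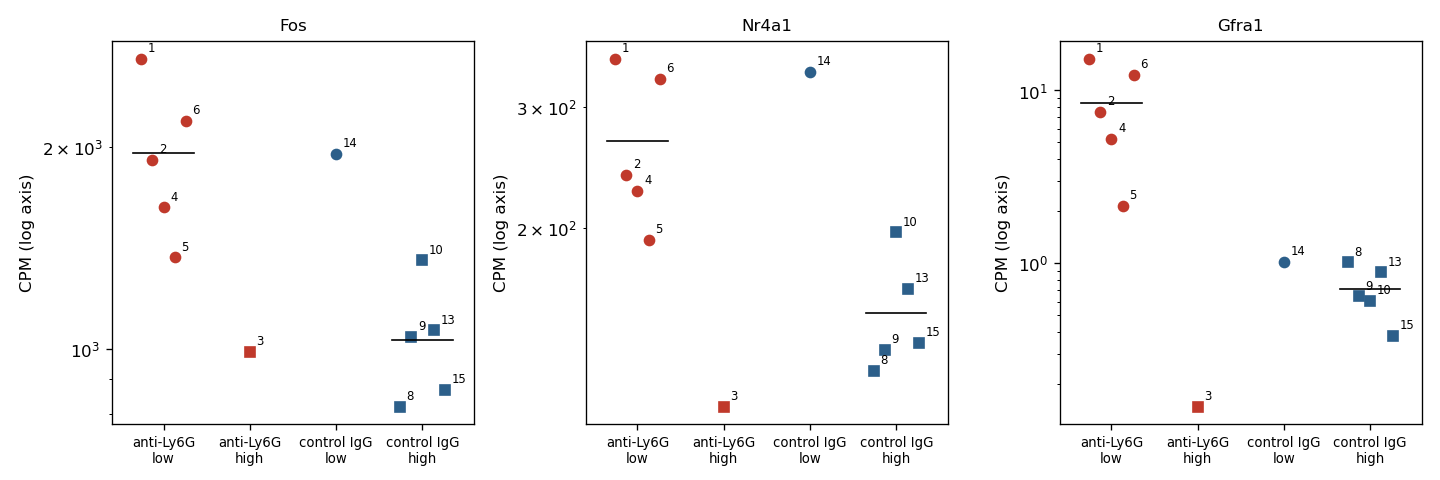
CPM of Fos, Nr4a1 and Gfra1 in each library on log axes, in columns for the 4 combinations of antibody and infiltration label, with numbers naming the libraries and bars the means of columns with 5 libraries. Fos averaged 1959 ± 464 CPM (SD) in the 6 low and 1022 ± 189 in the 6 high libraries, and each low library exceeded each high library for Fos and Gfra1. For Gfra1 this was nearly a tie between control IgG library 14, labelled low (1.015 CPM), and control IgG library 8, labelled high (1.011 CPM). The Fos gap was narrow too, with 1369 CPM in anti-Ly6G library 5, labelled low, and 1355 CPM in control IgG library 10, labelled high.

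With the antibody as a covariate, edgeR called 95 genes in the infiltration comparison, 47 higher and 48 lower in the low libraries. Nr4a1 was among them, with a log2 fold change of 1.23 (adjusted p = 0.0396), as were the neutrophil-recruiting cytokines Cxcl3 (-3.09, adjusted p = 0.0313) and Il1a (-2.67, adjusted p = 0.0450), chosen after their values were seen. Within an antibody group the label rests on library 3 or library 14: without library 3 the fit called 1 gene, which was not among the 95, and without library 14 it called 13, of which 4 were.

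None of the genes named in advance passed by edgeR in this comparison either. Pecam1, an endothelial adhesion molecule, stood at -0.86 ± 0.42 (adjusted p = 0.592), Vegfa at 0.34 ± 0.18 (0.615), Trp53 at -0.42 ± 0.23 (0.623) and Cd274 at 0.66 ± 0.45 (0.685). S100a9 and Csf3r stood at -0.91 ± 0.87 and -0.37 ± 0.45, Ptprc at -0.13 ± 0.38, and Cxcl1, Cxcl2 and Cxcl5 at -0.24 ± 0.44, -0.18 ± 0.46 and -0.51 ± 0.61. Hif1a (-0.03 ± 0.19), Slc2a1 (0.02 ± 0.15), Car9 (-0.03 ± 0.69), Snai1 (-0.21 ± 0.37), Sftpc (-0.15 ± 0.28), Mki67 (-0.12 ± 0.28) and Kras (-0.27 ± 0.18) also lay within their errors or close to them. The signs for Slfn4, Ptprc, Hif1a, Slc2a1, Car9, Cxcl1, Cxcl2 and Mki67 turned when certain libraries were left out, and that for Car9 also with library sizes alone (0.03) and with limma-voom (0.39).

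Markers of other cell types moved less than the endothelial list, and camera called none of the following lists in the infiltration comparison. Epithelial markers had 10 of 16 higher and a median of 0.02 (adjusted p = 0.933), alveolar type II markers 4 of 13 and -0.15 (0.181), and alveolar type I markers 5 of 10 and -0.04 (0.383). Club (4 of 8 higher, -0.24, 0.339), ciliated (5 of 9, 0.03, 0.933) and neuroendocrine markers (1 of 3, -0.08, 0.933) were likewise not called. Fibroblast markers had 4 of 15 higher and a median of -0.13 (0.134), lymphatic markers 2 of 5 and -0.22 (0.339), and muscle markers 4 of 6 and 0.34 (0.258). For pericyte markers (4 of 12 higher, -0.10, 0.966) and mesothelial markers (2 of 4, -0.09, 0.933) the median was negative while camera ranked the list upward. Pan-leukocyte markers had 1 of 12 higher and a median of -0.19 (0.176), macrophage markers 7 of 14 and -0.04 (0.467), T cell markers 3 of 3 and 0.29 (0.258), and B cell markers 2 of 5 and -0.11 (0.966). Erythroid markers had 2 of 7 higher and a median of -0.38 (0.332), and platelet markers 2 of 3 and 0.11 (0.966).

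The concordant comparison set the 5 anti-Ly6G libraries with low infiltration against the 5 control IgG libraries with high infiltration, so that both labels pointed the same way. Immediate early genes were higher in 14 of 14 cases with a median of 0.76, and endothelial markers lower in 20 of 20 with a median of -0.76. MHC class I genes (12 of 12 higher, 0.55) and interferon-stimulated genes (19 of 21, 0.35) were higher, and fibroblast genes (12 of 16 lower, -0.23) and mesenchymal genes (13 of 18, -0.25) lower. Camera called these 6 lists at the preset correlation (adjusted p 6.88e-18 for the immediate early and endothelial lists, 0.00592 for MHC class I and 0.0383 for each of the other 3). With an estimated correlation none passed: adjusted p = 0.265 with an estimated correlation for immediate early, 0.802 for interferon and 0.774 for the other 4, and fry called 0 lists.

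Atf3 had a log2 fold change of 1.14 ± 0.25 (SE, 5 against 5 libraries), with every low library above every high one, Fos 0.93 ± 0.21, Nr4a1 0.83 ± 0.19 and Fosb 0.87 ± 0.25, and 9 of the 14 immediate early genes passed when adjusted over the list alone. That number was 5 without library 1, 6 or 15. Sox17, Emcn, Ramp2 and Egfl7 stood at -1.14 ± 0.43, -1.08 ± 0.45, -0.98 ± 0.36 and -0.74 ± 0.26. The interferon-stimulated genes Gbp2 (1.30 ± 0.64), Cxcl10 (0.77 ± 0.39), Gbp3 (0.92 ± 0.52) and Cxcl9 (1.64 ± 1.02) were the members of smallest p, and B2m, Psmb9, Tap1 and H2-K1 stood at 0.67 ± 0.47, 0.82 ± 0.47, 0.70 ± 0.47 and 0.57 ± 0.43. Fibroblast genes Postn, Lum, Sparc and Fap stood at -0.64 ± 0.43, -0.83 ± 0.58, -0.31 ± 0.24 and -0.39 ± 0.31. Mmp3 (-2.99 ± 1.06), Vim (-0.79 ± 0.44) and Itga5 (-0.82 ± 0.46) of the mesenchymal list were lower, and Fn1 stood at 0.71 ± 0.33. Mmp3 was at -1.10 without library 10, and Cxcl9 at -0.0495 without library 4. The immediate early and endothelial calls held without each library in turn, with medians without library 4 of -1.25 for endothelial, -0.86 for fibroblast and -0.76 for mesenchymal genes. Interferon was lost without library 4 (median -0.0542, adjusted p = 0.8289), 5, 8 or 9, MHC class I without 4 (median 0.12, adjusted p = 0.348), 8 or 9, fibroblast without 1, 5, 6, 8 or 13 (0.132 to 0.393) and mesenchymal without 1, 5, 6, 8, 9 or 10 (0.111 to 0.538).

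No gene passed by edgeR among 15422 tested in the concordant comparison (smallest adjusted p 0.268). An unadjusted p under 0.05 was found for 847 genes, 515 higher and 332 lower, where chance gives 771. DESeq2 called 30 genes, 26 higher and 4 lower, limma-voom 0, and limma-voom with sample weights 3362, of which 1553 were higher. Gfra1 again had the smallest p, at 8.66 ± 5.39 CPM (SD, n = 5) against 0.721 ± 0.254, a log2 fold change of 3.59 ± 0.52 and an adjusted p of 7.79e-10 by DESeq2. It passed by edgeR without library 5 (adjusted p = 0.0236), and Scn7a, a sodium channel gene chosen after its values were seen, without library 4 (-2.53, 0.0433). Library 5 had the lowest Gfra1 level of the 5 anti-Ly6G libraries (2.15 CPM), so the Gfra1 pass without it is no separate support. Tpst1 averaged 18.2 ± 2.44 against 10.4 ± 1.13 CPM (0.80 ± 0.15, adjusted p = 0.000877 by DESeq2), and Slc38a4 41.7 ± 12.9 against 17.6 ± 5.44 (1.25 ± 0.26, 0.0158). The others among the 10 of smallest p were Fam26e (1.58 ± 0.33), Cpxm1, a carboxypeptidase-like gene (1.34 ± 0.30), Rrad, a small GTPase (1.07 ± 0.24), Sntb1, a syntrophin (0.81 ± 0.18), and Cyr61, a matricellular protein (0.77 ± 0.18), together with Atf3 and Fos. DESeq2 called 9 of these 10 and left out Cyr61 (0.0671). Of the 30 DESeq2 genes, 17 were also among its 47 in the infiltration comparison. In 143 genes (0.927%) the groups did not overlap, where chance gives 0.794%.

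Genes named in advance were again not called by edgeR in the concordant comparison. S100a8 stood at -0.68 ± 0.52, S100a9 at -0.74 ± 0.94, Csf3r at -0.28 ± 0.48 and Ptprc at -0.07 ± 0.41. Cxcl1, Cxcl2 and Cxcl5 stood at 0.23 ± 0.39, 0.45 ± 0.30 and -0.08 ± 0.54, and Hif1a, Vegfa, Slc2a1 and Car9 at 0.08 ± 0.18, 0.27 ± 0.20, 0.11 ± 0.17 and 0.41 ± 0.76. Pecam1 (-0.78 ± 0.43), Snai1 (-0.33 ± 0.39), Cd274 (0.62 ± 0.47), Sftpc (-0.33 ± 0.29), Mki67 (-0.22 ± 0.32), Kras (-0.12 ± 0.18) and Trp53 (-0.39 ± 0.23) had adjusted p of 0.854 to 0.928. The signs for Cxcl9, S100a9, Ptprc, Hif1a, Cxcl1 and Cxcl5 turned when certain libraries were left out, and that for Cxcl5 also with limma-voom (0.17).

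**Figure D4:**
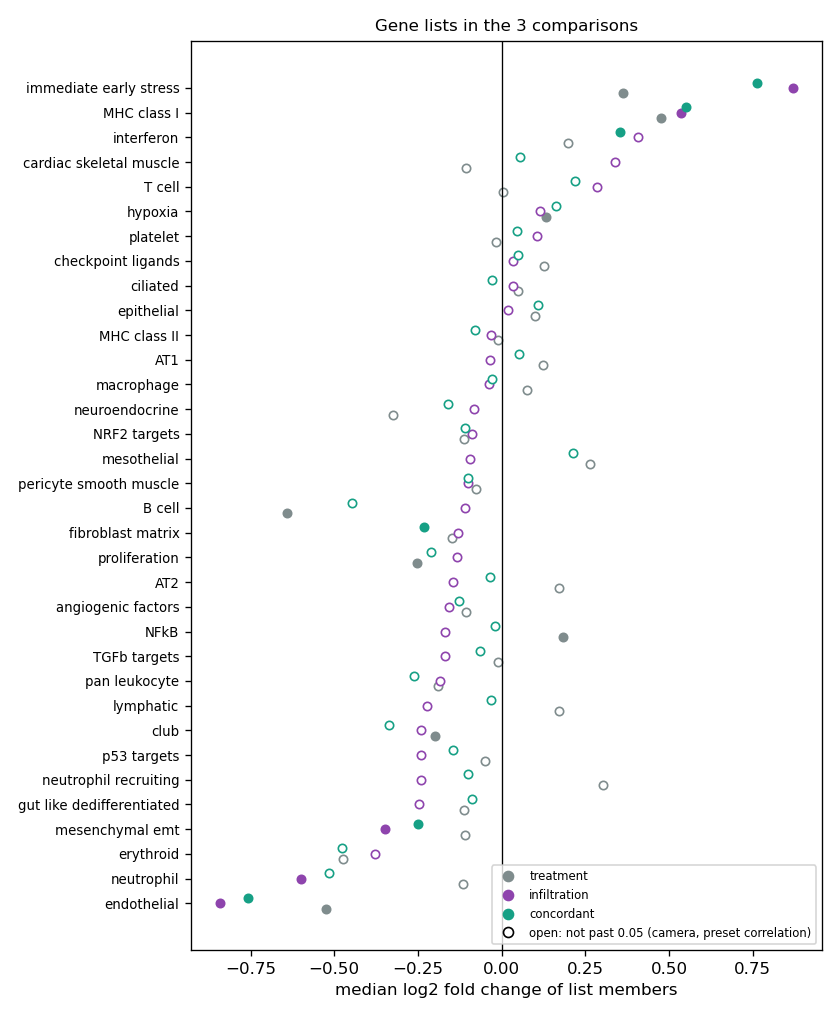
Median log2 fold change of the members of each tested gene list (horizontal axis) in the treatment, infiltration and concordant comparisons, with lists on the vertical axis. Filled points passed camera at the preset correlation of 0.01 (8, 5 and 6 lists) and open points did not; no list passed with an estimated correlation.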

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

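The tests of scaling, of cell mix and of the infiltration label for the immediate early genes, and of scaling and of the epithelial share for the endothelial markers, were chosen only after the results were seen.

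Immediate early and stress genes were higher in the low infiltration libraries, 14 of 14 with a median log2 fold change of 0.87. Library scaling, which shifts every gene alike, is argued against, since the lower quartile of the list, 0.65, lay above the upper quartile of all other genes, 0.20, by 0.447. A difference in depth is argued against as well: with every library thinned to the lowest total count, 12 of the 14 members passed over the list alone, with a median of 0.87. A different mix of cell types stays open: the highest median of the 15 cell type lists with at least 5 members was 0.339, for muscle markers, but its 6 members went both ways (SD 0.678, 2 lower). Cell handling before RNA extraction stays open as well, although a heat shock list written for this purpose did not differ between low and high libraries (exact permutation p = 0.978, 5 of 12 higher, median -0.03), because dissociation can induce immediate early genes without heat shock genes. The infiltration label rather than the antibody is a candidate explanation that the values allowed: permuting the label within antibody groups gave an exact p of 0.0278, the smallest of 36 arrangements, with a difference of 0.969, against -0.249 for the antibody within labels (exact p = 0.417), though it rests on library 3 and library 14 alone.

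Blood endothelial markers were lower in the low infiltration libraries, 20 of 20 with a median of -0.84. Library scaling is argued against, because the upper quartile of the list, -0.69, lay below the lower quartile of all other genes, -0.18, by 0.513. So is a difference in depth, as all 20 were lower with every library thinned to the lowest total count, with a median of -0.80. A larger share of epithelial cells, which would lower the markers of every other cell type alike, stays open. Of the 9 other non-epithelial cell type lists with at least 5 members, 8 had interquartile ranges above the endothelial range of -0.98 to -0.69. Their medians ran from -0.38 for erythroid to 0.34 for muscle markers. The exception was the neutrophil list, with a median of -0.60 and a lower quartile of -0.98. These ranges cannot decide the question, since they include anti-Ly6G library 4 and were not compared without it. Among low libraries it had the highest fibroblast, lymphatic, leukocyte, macrophage and erythroid scores. Fewer endothelial cells in the low libraries, or lower expression in them, may both account for the lower endothelial markers, and neither was tested. Within antibody groups the difference was -1.13 (exact permutation p = 0.0556), so an effect of neutrophils stays open as untested. This difference rests on library 3 and library 14 alone, and mostly on library 14. Control IgG library 14 scored 3.42, against 4.63 or more in the other control libraries. Anti-Ly6G library 3 scored 4.78, within the range of the other anti-Ly6G libraries (3.58 to 5.602).

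The limma-voom fit with sample weights called 1385 genes in the treatment and 1606 in the infiltration comparison, where edgeR called 0. A lower weight of anti-Ly6G library 3 is argued against: its weight was 0.335, but without it 2062 genes were called in the treatment and 2257 in the infiltration comparison. A high weight of the closest pair, anti-Ly6G libraries 1 and 6, may account for the calls: library 6 had a weight of 6.15 and library 1 of 2.58 in the treatment fit, and without library 6 the fit called 0 genes in both comparisons. These libraries had the smallest chi-square per degree of freedom of all pairs, 19.3 against at most 391, and the highest Spearman correlation, 0.995. No biological explanation for their closeness was tested.

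Other splits of the same libraries were drawn, 100 per comparison with the real one included, and chance was not excluded for the counts of lists by camera or of genes by DESeq2 and by limma-voom with weights. For genes by edgeR the real count was 0 in each comparison, which any split reaches (100 of 100), so these splits decide nothing. Another split called at most 309 genes (treatment and infiltration) and 257 (concordant). For lists by camera, 59 splits gave at least the real 8 in the treatment comparison, 88 at least the real 5 in the infiltration comparison and 78 at least the real 6 in the concordant one, with 18 the highest in another split and a median of 9, above all 3 real counts. For DESeq2, 68 splits gave at least the real 1, 12 at least the real 47 and 29 at least the real 30 (highest other 963, 963 and 968). For limma-voom with weights, 11 splits reached 1385, 12 reached 1606 and 12 reached 3362 (highest other 4126, 4126 and 4678). The splits that called 309, 118 and 257 genes point to a structure of the samples: in each of them libraries 1 and 6 lay on the same side and library 4 on the opposite side. That arrangement alone does not give such counts, since 19 of the 23 splits that had it, those with many genes included, called 0 genes in the treatment comparison, 19 of 23 in the infiltration comparison and 22 of 28 in the concordant comparison. The splits without it called at most 1, 1 and 0 genes.

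A library was marked where it stood far from the others of its group. This happened 45 times in 532 groups (8.46%), where chance flags about 1 in 20 independent groups, and it involved 31 measures and 9 libraries. Each measure was checked by antibody and by infiltration group, which share most libraries, so the same library could be flagged under both. Many genes were named because they differed between groups. The share of flags therefore cannot be set against chance. Highest and lowest below hold within the antibody group or infiltration group in which the library was marked, and not always over all libraries. Anti-Ly6G library 4 accounted for 15 of the 45: it was highest in hemoglobin share (0.115% of counts), in the leukocyte (3.32), macrophage (4.11), erythroid (5.6) and p53 target (4.63) scores, and in Hif1a (399 CPM), Emcn (41.9 CPM) and Sparc (1190 CPM), and lowest in Pard3 (117 CPM) and Fam26e (2.12 CPM). Anti-Ly6G library 3 accounted for 10: it was lowest in the neuroendocrine (0.12) and TGF-beta target (5.81) scores and in Trerf1 (1.59 CPM), Cpxm1 (1 CPM) and Fap (0.383 CPM), and highest in the NF-kappaB (6.68) and p53 target (4.62) scores and in Hk2 (245 CPM) and Ankrd37 (41.9 CPM). Control IgG library 14 accounted for 7: it was lowest in the TGF-beta target (5.44) and p53 target (4.27) scores, Sox17 (1.14 CPM) and Trp53 (4.83 CPM), and highest in Fam26e (6.37 CPM), Rrad (10.5 CPM) and Sntb1 (45.0 CPM). Anti-Ly6G library 2 was highest in the TMM factor (1.08) and lowest in Mt2 (168 CPM) and Sntb1 (17.4 CPM), and anti-Ly6G library 5 was lowest in Ier3 (78.3 CPM). Control IgG library 8 was highest in Ly6g (0.0349 CPM, which is 1 read) and S100a9 (2.82 CPM), and control IgG library 9 was lowest in Mt2 (58.6 CPM) and Jund (27.5 CPM). Control IgG library 13 was lowest in Bhlhe40 (212 CPM), and control IgG library 15 was highest in the NRF2 target score (6.33) and Ptprc (10.1 CPM).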

How the results depend on the processing

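The fits to the deposited log2 values, to libraries 1 and 6 summed, and with the covariates without library 3 or 14 were chosen only after the data were seen. Of 185 results, 161 had no reversed value under any alternative run and 113 were classed as the same in all of them. Of 3110 values under alternatives, 2882 were classed as the same. Of the rest, 107 lost and 34 gained the threshold, 35 counts or levels moved and 52 reversed. A small change in a count was classed as the same, such as 10 treatment lists without library 2 against 8 in the main fit. No named gene passed by edgeR in the main fit, so one that again did not pass kept its side of the threshold. These shares therefore do not measure how firm the results are. The other scalings moved the median of all genes by less than 0.1. Where a cause is not named, the cause was not tested.

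Gene counts of 0 by edgeR became, in the treatment comparison, 1 with DESeq2, 1385 with limma-voom and sample weights, 9 with the infiltration label as a covariate, 1 with that covariate and library 3 left out and 1 with library 14 left out; in the infiltration comparison 47, 1606, 95 with the antibody as a covariate, 1 without library 3 as well and 13 without library 14; and in the concordant comparison 30 and 3362. Leaving out each library gave 0 to 90 genes in the infiltration comparison (90 without library 4), 0 to 1 in the concordant one, and 0 throughout in the treatment one. With an estimated correlation 0 lists were called in each comparison, and with fry 0, 1 and 0. Leaving out each library gave 3 to 9 lists in the infiltration comparison (3 without 5, 8 or 9, 9 without 4) and 2 to 9 in the concordant one (2 without 8, 4 without 1, 9 without 4). With the infiltration label as a covariate 5 treatment lists were called, and the medians of the endothelial (0.29), MHC class I (-0.00202) and immediate early (-0.37) lists reversed. Immediate early members past the threshold over the list alone fell from 12 to 3 in the infiltration comparison with the antibody as a covariate and library 14 left out, and from 9 to 5 in the concordant comparison with a leukocyte covariate and with libraries 1 and 6 summed, where fewer samples are fitted; leaving out each library gave 5 to 10. Library sizes alone, a leukocyte covariate and libraries 1 and 6 summed each ended the concordant fibroblast (adjusted p 0.0583, 0.270 and 0.145) and mesenchymal (0.0583, 0.0559 and 0.145) calls and the treatment club call (0.0620, 0.0527 and 0.200), and summing also ended the cell cycle call (0.0530) and the infiltration neutrophil call (0.144). Of these settings, library sizes alone gave a club median of -0.286, the leukocyte covariate -0.198 and summing -0.111, against -0.200 in the main fit. The concordant interferon median reversed without library 4 (-0.0542, up to 0.52 without another library), and the fibroblast median without library 8 (0.0455, down to -0.86). The neutrophil marker level, low minus high, ranged from -0.633 (without library 4, where the unadjusted exact p was 0.0130) to -0.293 when each library was left out.

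Some log2 fold changes reversed when a library was left out. In the treatment comparison they ranged from -1.32 to 0.59 for S100a9, -0.51 to 0.0635 for Csf3r, -0.37 to 0.23 for Ptprc, -0.0182 to 0.21 for Vegfa and -0.0305 to 0.20 for Kras. In the infiltration comparison they ranged from -2.37 to 0.30 for Slfn4, -0.56 to 0.0462 for Ptprc, -0.21 to 0.0566 for Hif1a, -0.0607 to 0.0872 for Slc2a1, -0.31 to 0.36 for Car9, -0.52 to 0.0553 for Cxcl1, -0.34 to 0.24 for Cxcl2 and -0.27 to 0.0448 for Mki67. In the concordant comparison they ranged from -0.0495 to 1.93 for Cxcl9, -2.14 to 0.27 for S100a9, -0.53 to 0.14 for Ptprc, -0.12 to 0.14 for Hif1a, -0.0195 to 0.62 for Cxcl1 and -0.37 to 0.59 for Cxcl5. Ptprc in the treatment comparison was -0.0220 with library sizes alone and -0.12 with limma-voom, Car9 in the infiltration comparison 0.0320 and 0.39, and Cxcl5 in the concordant comparison 0.17 with limma-voom. At this depth Ly6g had 4 reads in 12 libraries, too few to show a change. The CD45 gate removes neutrophils as well, and these limits were not compared.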

Other observations

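The genes and groups below were chosen after their values were seen, and of the tests only that of the circadian clock over all 12 libraries was fixed before the values it measures were known. The test of the clock within antibody groups was chosen after.

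With the antibody in the model, 95 genes differed by infiltration label, of which 2 were on the list of neutrophil-recruiting cytokines. Rorc, which encodes a nuclear receptor, was higher in the low infiltration libraries (log2 fold change 1.67, adjusted p = 0.0108), and Fkbp5, a glucocorticoid-induced gene, was lower (-1.58, adjusted p = 0.0393). Cxcl3 and Il1a, which draw in or activate neutrophils, were lower, at -3.09 and -2.67. Ereg, an epidermal growth factor receptor ligand, was lower by label (-1.49, adjusted p = 0.0322) and higher with anti-Ly6G in the model with both terms (1.90, adjusted p = 0.0328). All 9 genes called for the antibody in that model were among the 95 called for the label. These calls rest on library 3 and library 14, the only libraries that part antibody and label: the fit without library 3 called 0 of the 95 genes, and the fit without library 14 called 4 of them.

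Without anti-Ly6G library 4, whose leukocyte, macrophage and endothelial scores were the highest among low infiltration libraries, the infiltration comparison called 77 lower genes, of which 7 were on the endothelial list. Removing the low library with the highest endothelial score lowers the endothelial level of that group, so these calls are no separate support. The 77 included the receptors Tek (-1.62), Kdr (-1.51), Calcrl (-1.74), Acvrl1 (-1.24) and S1pr1 (-1.54), the transcription factors Tal1 (-1.55), Gata2 (-1.57) and Foxf1 (-1.59), and the lymphatic and sinusoidal gene Lyve1 (-1.38), each with an adjusted p between 0.0372 and 0.0478. Fos (0.98, adjusted p = 0.0449) and Nr4a1 (1.01, adjusted p = 0.0427) were among the 13 higher genes.

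The order of genes in the deposited log2 table followed the infiltration comparison. The Spearman correlation across genes between position in the table and the edgeR p was 0.984 for the infiltration comparison, 0.688 for the concordant and 0.148 for the treatment comparison, and 97 of the 100 genes of smallest p for infiltration stood in the first 200 positions. Genes are not independent replicates, so these values are given without a test.

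Dbp and Tef, output genes of the circadian clock, were higher in the low infiltration libraries with the antibody in the model (2.35 and 1.402, adjusted p = 0.0396 and 0.0322). A different phase of the circadian clock at harvest may account for this, and was tested on other clock genes, as 6 genes expected to rise with Dbp minus 5 expected to fall. Over all 12 libraries the score was higher by 0.456 in the low libraries (exact permutation p = 0.128), which decides nothing. Within antibody groups, the form that matches the model, it was higher by 0.998 (exact permutation p = 0.0278, the smallest of 36 arrangements), so the values allowed a different clock phase as a candidate explanation, though this rests on library 3 and library 14 alone. Nr1d1 (0.94 ± 0.24, SE) and Per2 (0.91 ± 0.37) went with Dbp (1.38 ± 0.50) and Tef (0.84 ± 0.26), each with an adjusted p of 0.583, and Bhlhe41 went the other way (-0.93 ± 0.53). The labels give no time of harvest.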
